A study of Homo sapiens with 4 samples.

How the data were processed

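In situ Hi-C maps of HCT116, an established human colorectal carcinoma line, were used from 4 libraries: 2 of wild type cells and 2 of cells depleted of NuMA, a large structural protein of the interphase nucleus that also organises spindle poles in mitosis. Group and replicate number were taken from the genotype and title labels. Nothing in the labels says whether the libraries of a group came from separate cultures. The p-values that compare libraries thus rest on the spread between these libraries, which may be technical. Where the text says so, that spread was pooled over all bins. The exact p-values of contacts pooled by genotype, given in a closing section, measure counting error only.

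Per the submitters' processing notes, reads were handled with HiC-Pro on build hg19. Its version, the mapping settings and the filters are not given in the sources used here. Each library was deposited as 4 contact matrices with bins of 40, 150, 500 and 1000 kb. The deposited values are a balanced contact signal for each pair of bins: the row sums of kept bins were equal within a library, as iterative correction gives, and the total of a matrix was a whole number that followed the depth of the library. Balancing was done within a library and sets no scale between libraries. The comparisons therefore used shares, ratios or observed over expected values within a library. The matrices have no header and no bin positions. The hg19 lengths of chromosomes 1 to 22, X, Y and M gave the highest bin number at all 4 bin sizes, and positions were assigned from them, counted from 1. Chromosome Y and mitochondrial DNA were left out of the comparisons. No gene annotation of hg19 was used here, so regions are given by position, no gene is named and the planned gene lists were not tested.

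Whole contacts were recovered from the balanced signal of the deposited matrices by finding for each bin the factor that makes its values whole. At 40 kb, 100.0% of the bin pairs of each library came within 0.02 of a whole number. Chromosomes 1 to 22 and X then held 18974647 and 45384933 contacts in wild type libraries 1 and 2, and 7851011 and 48886743 contacts in NuMA-depleted libraries 1 and 2. At 150 and 500 kb at least 99.4% of pairs were whole, and at 1000 kb recovery was not attempted. The recovered contacts served to give depth, to replace balanced values in alternatives and to thin each map at random to the contacts of the shallowest library, with the balancing factors kept. Confidence intervals of shares are 95% Wilson intervals. They cover counting error only.

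Bins kept by balancing in all 4 libraries were used, 69625 at 40 kb and 5663 at 500 kb. Compartments were set once for all libraries from the first eigenvector of the mean observed over expected map of each chromosome at 500 kb. A was the sign linked by contacts to the gene-rich chromosomes 17, 19 and 22. Compartment strength was the mean of A with A and B with B contacts over A with B contacts, and the compartment score of a bin was the log2 ratio of its contacts with A bins to those with B bins at 2 Mb or more. The distal-to-local ratio was the log2 ratio of cis signal over 3 Mb away to cis signal within 3 Mb. The insulation score was the log2 mean signal of a 400 kb diamond at a 40 kb bin over the chromosome mean. It was taken for diamonds with a mean of at least 10 non-zero pairs. A higher score means more contacts across the bin and thus weaker insulation. Boundaries were local minima of the mean insulation score at least 0.1 deep, and domains of 200 kb to 3 Mb lay between neighbouring boundaries. Their value was the log2 ratio of distance-corrected signal inside to that across the borders. Chromosome pairs took the log2 ratio of observed signal to the product of the chromosomes' margins at 1000 kb.

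Per-bin, per-domain and per-pair values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05), and single values per library with an exact two-sided permutation test over the 6 assignments of 2 against 2 libraries. The smallest p that test can give is 0.333, so no single value could pass. The design, the tests, the rule for named regions and the alternatives, apart from those the closing section names as chosen later, were fixed before the data were examined. The rule named the 10 smallest p in each direction among features past the threshold whose groups did not overlap, with neighbours within 1 Mb merged, and where none passed the 3 smallest p in each direction as values that did not pass. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest.

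The functions were tested on simulated data. With 200 changed features among 5663, limma recovered 24.0% of compartment scores changed by 0.5 on the log2 scale and 97.0% of those changed by 1, with 4 false calls. For the distal-to-local ratio these shares were 85.0% and 100.0%, with 0 false calls. With 200 changed among 68879 insulation scores they were 98.0% and 100.0%, with 8 false calls, and with 200 changed among 2849 domains they were 99.0% and 100.0%, with 9. With 50 changed among 253 chromosome pairs both shares were 100.0%, with 2 false calls. The simulated noise was set for each library from the real differences but was the same for every feature. Real bins, which differ in their contacts, do not share this.

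Alternatives were other bin sizes, windows, filters and definitions, whole or thinned contacts in place of balanced signal, other scalings, the replicate number as a block and leaving out each library. Whether NuMA was depleted was not checked here, since contact maps do not measure a protein.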

Results

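Genome-wide chromatin contacts were mapped by in situ Hi-C in HCT116 cells with and without NuMA. The series asks how loss of this nuclear scaffold protein alters the spatial arrangement of chromosomes. Each genotype had 2 libraries. Depth was unequal: the wild type libraries held 18974647 and 45384933 contacts and the NuMA-depleted libraries 7851011 and 48886743, so that the first NuMA-depleted library carried the least information about any single region.

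Contacts within chromosomes made up most of the signal in both genotypes. The cis share of the balanced signal was 75.7% ± 3.15 (SD, n = 2) in wild type and 77.2% ± 3.66 (SD, n = 2) in NuMA-depleted cells. The libraries of a genotype lay further apart than the genotypes did, at 73.4% and 77.9% in wild type and 79.8% and 74.6% after depletion. The difference of 1.53 percentage points gave p = 0.667 in the exact permutation test, and without wild type 1 or without NuMA-depleted 1 it turned to -0.698 and -1.06. In whole contacts the share of wild type 1 was 73.0% (95% Wilson interval 72.97 to 73.01) and that of NuMA-depleted 1 was 79.4% (79.39 to 79.44), so counting error was far below the spread between libraries.

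NuMA-depleted 2 had fewer contacts at short and more at long distances than the other 3 libraries, and NuMA-depleted 1 did not share this shift. Pairs 40 to 200 kb apart held 32.1% ± 0.513 of the cis signal in wild type and 31.6% ± 2.36 in NuMA-depleted cells (SD, n = 2), and the depleted libraries lay on either side of wild type at 33.2% and 29.9%. Pairs 200 kb to 1 Mb apart held 27.1% ± 0.197 in wild type and 26.3% ± 0.706 after depletion. This was the band in which both depleted libraries, at 26.8% and 25.8%, lay below both wild type libraries, at 27.2% and 26.9%. In 150 kb bins, where the nearest band was 300 kb to 1 Mb, the genotypes overlapped, with 38.9% and 35.6% after depletion against 39.0% and 38.2% (exact p = 0.667). The bands of 1 to 3 Mb (13.8% ± 0.261 against 14.02% ± 0.546), 3 to 10 Mb (9.87% ± 0.333 against 10.4% ± 0.929), 10 to 50 Mb (13.4% ± 0.175 against 13.8% ± 1.14) and over 50 Mb (3.76% ± 0.0592 against 3.86% ± 0.448) overlapped between genotypes. The exact p was 0.333 for the band of 200 kb to 1 Mb, the smallest the design allows, and between 0.667 and 1.00 for the others, with every adjusted p at 1.00. Without NuMA-depleted 2 the difference at 200 kb to 1 Mb went from -0.759 to -0.260 percentage points, and without NuMA-depleted 1 to -1.26. The differences of the other bands changed sign without NuMA-depleted 2, from -0.548 to 1.12 percentage points at 40 to 200 kb, from 0.228 to -0.158 at 1 to 3 Mb, from 0.526 to -0.131 at 3 to 10 Mb, from 0.449 to -0.360 at 10 to 50 Mb and from 0.105 to -0.212 over 50 Mb.

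**Figure D1:**
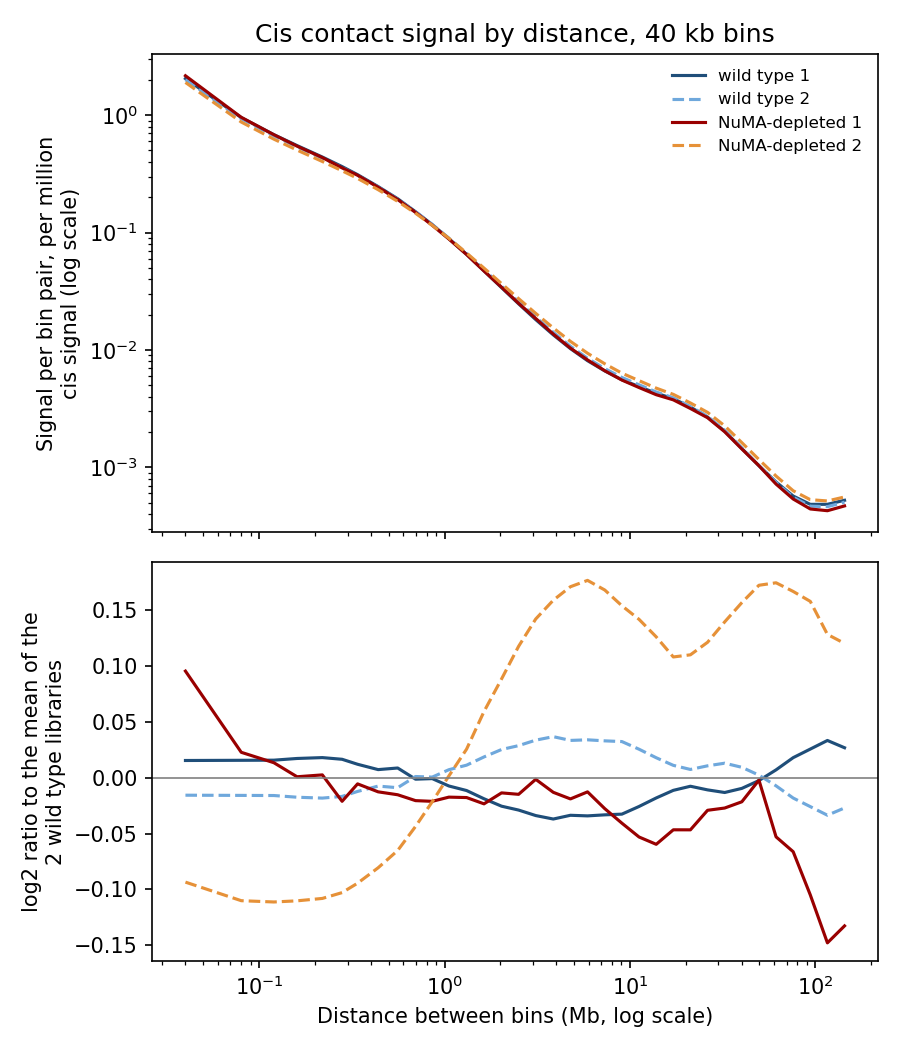
Cis signal per pair of 40 kb bins, scaled to the same total cis signal in each library, against the distance between the bins in Mb, 1 line per library, with both axes on a log scale in the upper panel. The lower panel gives the log2 ratio of each library to the mean of the 2 wild type libraries: NuMA-depleted 2 lay 0.11 below at 0.12 Mb and 0.18 above at 5.32 to 6.56 Mb, while NuMA-depleted 1 lay 0.10 above at 0.04 Mb, 0.01 below at 5.32 to 6.56 Mb and 0.15 below at 104.56 to 129.32 Mb.

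The division of chromosomes into A and B compartments was as strong in NuMA-depleted as in wild type cells within the spread of the libraries. A was named by contacts alone, so whether it was the active compartment was not tested. It held 46.7% to 77.7% of the bins of single gene-poor chromosomes and 49.7% to 69.0% of those of single gene-rich chromosomes. Loci contacted their own compartment more than the other by 1.78 ± 0.102 in wild type and 1.82 ± 0.0235 after depletion (SD, n = 2, ratio of mean observed over expected signal). The library values were 1.71 and 1.85 in wild type and 1.83 and 1.80 after depletion. Contacts of A with A bins stood at 1.25 ± 0.0171 and 1.26 ± 0.00991 times the expectation, of B with B bins at 1.27 ± 0.0366 and 1.28 ± 0.00242, and of A with B bins at 0.710 ± 0.0257 and 0.6995 ± 0.00699, in wild type and NuMA-depleted cells. The exact p for compartment strength was 1.00, and without wild type 1 the difference of 0.0375 turned to -0.0349.

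No single 500 kb bin changed its compartment score past the threshold. Limma called 0 of 5663 bins, with 140 bins at an unadjusted p under 0.05, and 95% of the differences lay between -0.33 and 0.35 on the log2 scale. The 3 bins with the smallest p among higher scores, none of which passed, were X from 40000001 to 40500000 (log2 difference 0.84 ± 0.19 SE), chromosome 2 from 241000001 to 241500000 (0.94 ± 0.23) and chromosome 22 from 16500001 to 17000000 (0.64 ± 0.18). The 3 among lower scores lay on distal chromosome 4, from 175000001 to 175500000 (-0.77 ± 0.21), from 190000001 to 190500000 (-0.71 ± 0.20) and from 160000001 to 160500000 (-0.66 ± 0.18). The adjusted p of each of the 6 was 0.999. Leaving out each library gave ranges of 0.62 to 1.06, 0.47 to 1.42 and 0.48 to 0.79 for the higher bins in this order. For the lower bins they were -1.07 to -0.47, -0.98 to -0.43 and -0.89 to -0.43. Without NuMA-depleted 2, which leaves the shallowest library alone in its group and assumes that it varies like the others, 59 bins were called.

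Few bins switched compartment. The eigenvector of 29 of 5663 bins had one sign in both wild type libraries and the other in both NuMA-depleted libraries, 24 from B to A and 5 from A to B. At equal contacts these counts were 46 and 28, and in 150 kb bins 147 and 53. The other ways of splitting the libraries into pairs gave 80 and 20 such bins in the main setting. They gave 80 and 52 at equal contacts and 314 and 141 in 150 kb bins. The split by genotype therefore did not stand out from the others. The bin with the largest switch, chromosome 4 from 175000001 to 175500000, went from A to B with eigenvector values of 0.661 and 0.188 in wild type and -0.462 and -0.232 after depletion. It was the 1 bin of the 29 with a change over 0.5. Between libraries the eigenvectors correlated at 0.969 to 0.993 across bins, which are not independent.

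The balance of distal to local contacts changed past the threshold in 2 of 5663 bins, both near a centromere. At chromosome 22 from 16500001 to 17000000 the log2 ratio of contacts beyond 3 Mb to those within 3 Mb rose by 0.62 ± 0.13 SE, from -2.60 and -2.35 in wild type to -2.09 and -1.63 after depletion (limma adjusted p = 0.00284). At chromosome 9 from 44500001 to 45000000 it fell by 0.85 ± 0.13 SE, from 4.53 and 3.45 to 2.92 and 3.37 (adjusted p = 1.16e-07). The prior degrees of freedom of limma were infinite here, so every bin had the same SE. That SE and the p-values reflect the spread over all bins and not that of the called bin. At the chromosome 9 bin the wild type libraries lay further apart than the genotype means. This bin had a dropped bin within 500 kb and 4 to 29 local contacts per library. Over all bins the mean ratio was -0.75 and -0.72 in wild type and -0.77 and -0.56 in NuMA-depleted libraries, and 43 bins had an unadjusted p under 0.05. The other two ways of splitting the libraries into pairs gave 2 calls each. The count was 0 without wild type 1, 1 without wild type 2, 2026 without NuMA-depleted 1 and 60 without NuMA-depleted 2. The chromosome 22 call ended without wild type 1 (log2 difference 0.49 ± 0.20 SE, adjusted p = 1.00) and without wild type 2 (0.74 ± 0.20, 0.675), where the SE rose, with array weights (0.62 ± 0.15, 0.0705) and with quantile normalization (0.50 ± 0.08, 0.0657), and without NuMA-depleted 2 it was 0.39 ± 0.08. The chromosome 9 call ended without wild type 1 (-0.31 ± 0.20, 1.00), with median centring (-0.92 ± 0.20, 0.466), with quantile normalization (-0.26 ± 0.11, 0.998) and at equal contacts (-0.51 ± 0.14, 0.397), and without wild type 2 the difference was -1.39 ± 0.20.

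Local insulation, the depletion of contacts across a locus, differed past the threshold at 1 region. Of 68879 bins of 40 kb, limma called 2, side by side on the short arm of X. Both had a higher score after depletion, which means weaker insulation. At X from 3680001 to 3720000 the insulation score rose by 0.86 ± 0.09 SE, from -2.63 and -2.53 in wild type to -1.61 and -1.82 after depletion, and at X from 3720001 to 3760000 it rose by 0.73 ± 0.08, from -2.50 and -2.45 to -1.70 and -1.79 (adjusted p = 0.0170 for both). Their diamonds lay beside dropped bins and held 14 to 70 and 15 to 82 contacts per library. No bin fell past the threshold, 3049 bins had an unadjusted p under 0.05, and 95% of the differences lay between -0.18 and 0.17. Quantile normalization ended both calls without a smaller difference, at 1.00 ± 0.12 SE and 0.79 ± 0.11 (adjusted p = 0.0818 and 0.145), and 800 kb diamonds ended both at 0.46 ± 0.08 (0.718). At equal contacts the second bin stood at 0.22 ± 0.19 (0.995) and the first was not tested, and with 200 kb diamonds or at least 30 non-zero pairs neither was tested and no other bin was called. Leaving out a library gave 3 calls without wild type 1, 11 without wild type 2, 22 without NuMA-depleted 1 and 3490 without NuMA-depleted 2.

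Domain boundaries were as deep in NuMA-depleted as in wild type cells within the spread of the libraries. Over 2942 boundaries the mean depth of the insulation minimum was 0.96 ± 0.0038 in wild type and 0.98 ± 0.060 after depletion (log2, SD, n = 2). The depleted libraries lay on either side of wild type at 1.02 and 0.94, against 0.96 and 0.96. The exact p was 1.00. The difference of 0.021 turned to -0.022 without NuMA-depleted 1, to -0.026 with boundaries set from wild type alone and to -0.0022 with 800 kb diamonds. With 200 kb diamonds it was 0.054.

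Contacts inside domains were not detectably altered. The 2849 domains had a median length of 800 kb, and the median log2 ratio of signal inside a domain to that across its borders was 0.71 and 0.73 in wild type and 0.74 and 0.70 in NuMA-depleted libraries. Limma called 0 domains, 130 had an unadjusted p under 0.05, and 95% of the differences lay between -0.19 and 0.19. The domains with the smallest p, none of which passed (adjusted p = 0.986), had higher ratios on chromosome 20 from 21640001 to 22280000 (log2 difference 0.29 ± 0.08 SE), X from 38080001 to 38480000 (0.38 ± 0.11) and chromosome 10 from 69560001 to 70080000 (0.45 ± 0.14). Those with lower ratios were on chromosome 5 from 57800001 to 58320000 (-0.32 ± 0.09), X from 45040001 to 45600000 (-0.33 ± 0.10) and chromosome 14 from 31040001 to 31880000 (-0.26 ± 0.08). Leaving out each library gave ranges of 0.21 to 0.36, 0.17 to 0.58 and 0.15 to 0.76 for the domains with higher ratios in this order. For those with lower ratios they were -0.42 to -0.21, -0.45 to -0.21 and -0.29 to -0.23. Without NuMA-depleted 1 there was 1 call, and without NuMA-depleted 2 there were 227.

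Contacts between whole chromosomes differed little between the genotypes. None of the 253 chromosome pairs passed in limma, 1 pair had an unadjusted p under 0.05, and 95% of the differences lay between -0.05 and 0.05 on the log2 scale. The pair with the smallest p was 16 with X, at -0.06 and -0.07 in wild type and -0.11 and -0.10 after depletion. The pairs with the next smallest p among lower contacts were 12 with 21 (log2 difference -0.06 ± 0.03 SE) and 13 with 17 (-0.05 ± 0.02). Those with the smallest p among higher contacts were 6 with 14 (0.03 ± 0.02), 12 with 22 (0.03 ± 0.02) and 15 with 19 (0.04 ± 0.02), and the adjusted p of each was 1.00. Leaving out each library gave -0.048 to -0.036 for 16 with X, -0.089 to -0.040 for 12 with 21 and -0.067 to -0.025 for 13 with 17. The ranges were 0.023 to 0.039 for 6 with 14, 0.019 to 0.038 for 12 with 22 and 0.013 to 0.071 for 15 with 19.

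Classes of regions set before the data were examined differed between the genotypes by at most 0.019 on the log2 scale. Relative to the mean of all bins, the distal-to-local ratio of bins within 5 Mb of a chromosome end was -0.41 ± 0.0030 in wild type and -0.40 ± 0.0038 after depletion (log2, SD, n = 2), and both depleted libraries lay above both wild type libraries. That difference of 0.016 was 0.0064 within 10 Mb. The differences were 0.019 for the gene-rich chromosomes, 0.011 for the acrocentric chromosomes, 0.0034 for A compartment, 0.0026 for the gene-poor chromosomes, -0.0050 for B compartment and -0.0070 near the centromere gap. For the insulation score they were 0.0084 near chromosome ends, 0.0068 near the centromere gap, 0.0013 and -0.0013 for the gene-rich and gene-poor chromosomes, -0.00063 for the acrocentric chromosomes, and 0.00014 and -0.00020 for A and B compartment. A and B together hold all bins, so that in each measure the value of B follows from that of A. The insulation score is scaled to the mean of each chromosome. Classes made of whole chromosomes are thus held near the mean of all bins, and their insulation values cannot show a shift of those chromosomes. The exact p was 0.333 for the distal-to-local ratio at chromosome ends and for insulation of the acrocentric chromosomes, with adjusted p of 0.933. The latter is such a class of whole chromosomes, so nothing is drawn from it. In the other values the groups overlapped. Apart from the values with an exact p of 0.333, each difference changed sign or moved by over 1.5 times without 1 library. Without wild type 1, wild type 2, NuMA-depleted 1 and NuMA-depleted 2 in turn, the distal-to-local ratio of the gene-rich chromosomes was -0.0059, 0.044, 0.040 and -0.0018, insulation near chromosome ends 0.0042, 0.013, 0.014 and 0.0027, near the centromere gap 0.012, 0.0016, 0.0102 and 0.0034, on gene-rich chromosomes 0.00050, 0.0021, 4.2e-06 and 0.0026, and on gene-poor chromosomes -0.0011, -0.0015, -0.00018 and -0.0025.

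**Figure D2:**
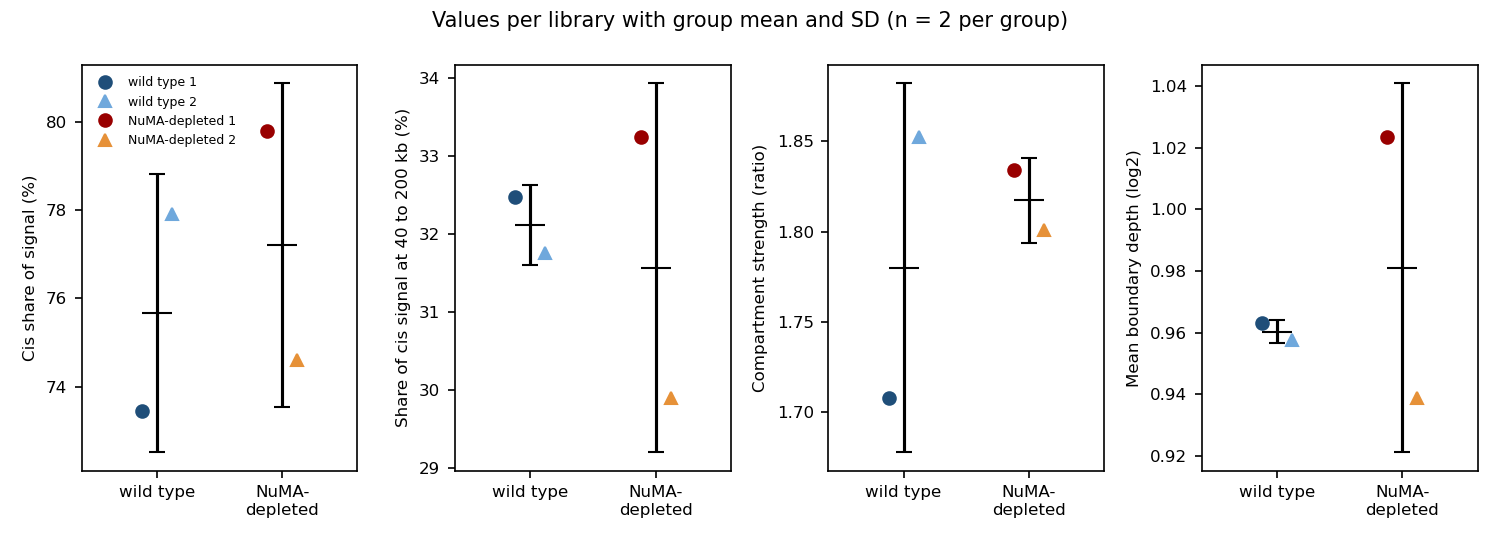
Cis share of signal (%), share of cis signal at 40 to 200 kb (%), compartment strength (ratio) and mean boundary depth (log2) for each library, with the mean and SD of each genotype (n = 2) as bars. The axes do not start at 0. The genotypes overlap in all 4 panels.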

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

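The tests weighed here were chosen after the results were seen, except the removal of a background from wild type 1. Contacts between mitochondrial and nuclear DNA lay outside the comparisons, and NuMA-depleted 2 had 1065 of them per 1000000 contacts (95% Wilson interval 1055 to 1074), above 542 and 676 in the wild type libraries, while NuMA-depleted 1 had 128.

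NuMA-depleted 2 had fewer contacts below 0.6 Mb and more beyond 1.2 Mb than the other 3 libraries. Depth is argued against by wild type 2, which had nearly the same depth: NuMA-depleted 2 held 7.72% more contacts and lay 1.86 percentage points lower in its share of cis signal at 40 to 200 kb (difference -1.86), where the slope between the wild type libraries gives -0.0618. Random ligation set by the distances beyond 84 Mb would give a rise of 0.0083 on the log2 scale at 5.3 to 6.6 Mb, where it was 0.18 and the wild type libraries differed by 0.07. More cells in mitosis, which lack very distal contacts, would give no rise beyond 20 Mb, where the highest was 0.17 with 0.01 between the wild type libraries. Each of these was weighed as the sole cause, so more mitotic cells together with random ligation were not tested and stay open. The high rate of contacts between mitochondrial and nuclear DNA in NuMA-depleted 2 was not part of this weighing. An unequal depletion of NuMA or a difference in library preparation may also account for the shift, and these maps do not part them.

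Wild type 1 had the weakest compartments, with a strength of 1.71 against 1.80 to 1.85 in the others. Depth is argued against by the depleted libraries, whose depth differed 6.23 times: the shallow one lay 0.0333 above the deep one, where the slope between the wild type libraries gives -0.303. A uniform background of random ligation could lower it: taking off the 25.9% of its signal between chromosomes that brings its A with B contacts between chromosomes to the mean of the others raised the strength to 1.76, short of their range. Random ligation as the whole cause thus stays open, and no biological explanation was tested, since both wild type libraries carry the same label.

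The 4 called bins differed in how far counting error may explain them. In the pooled contacts of each genotype the exact p was 0.00607 and 0.00570 for the X bins, values that chance gives in many of 68879 bins, and 0.312 for the chromosome 9 bin among 5663. There, few contacts are a candidate explanation, and 3 of the 4 bins lay within 500 kb of a dropped bin, as 7.60% of tested 40 kb bins and 1.55% of tested 500 kb bins did. For the chromosome 22 bin the exact p was 1.25e-06, which multiplied by the bins tested is 0.00706 and argues against counting error alone. The distal shift of NuMA-depleted 2 alone is argued against by the difference after median centring, 0.55 ± 0.08 SE against 0.62 ± 0.13 before (limma adjusted p = 0.0321). Quantile normalization, however, at 0.50 ± 0.08, ended the call (0.0657). The prior degrees of freedom fell from infinite to 14.6 with median centring and to 11.5 with quantile normalization. Counting error and the distal shift together were not tested, so a NuMA effect stays open.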

How the results depend on the processing

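Array weights, the crossed pairing, switching at equal contacts and some scalings were chosen after the data were seen. Of 182 values of comparisons under an alternative that could move them, 133 kept their direction and their side of the threshold or stayed within 1.5 times the count. No single value per library could pass the threshold, so for these only the direction counted and not the size. The difference at 200 kb to 1 Mb, -0.759, was thus counted as kept at -0.260 without NuMA-depleted 2. Boundary strength turned to -0.0022 with 800 kb diamonds and -0.026 with boundaries of wild type alone, and the distal-to-local ratio near the centromere gap turned to 0.0025 within 10 Mb, where that near chromosome ends was 0.0064 in place of 0.016 and insulation near the centromere gap 0.0035 in place of 0.0068. Calls of the distal-to-local ratio came to 1 with array weights, which kept the chromosome 9 bin, 1 after median centring, which kept the chromosome 22 bin, 0 after quantile normalization and 4 at equal contacts, among them the chromosome 22 bin but not the chromosome 9 bin. Insulation calls fell to 0 with 200 kb or 800 kb diamonds, 30 non-zero pairs, quantile normalization or equal contacts, where some settings did not test the X bins, and having no minimum of pairs removed no bin. Switched bins came to 200 at 150 kb, 74 at equal contacts (46 from B to A and 28 from A to B) and 1 with a change over 0.5. The cause was not tested in any of these.

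Leaving out each library gave ranges of -1.06 to 4.12 for the cis share, -0.158 to 0.614, -0.360 to 1.26, -0.131 to 1.18, -2.22 to 1.12, -1.26 to -0.260 and -0.212 to 0.421 for the bands of 1 to 3 Mb, 10 to 50 Mb, 3 to 10 Mb, 40 to 200 kb, 200 kb to 1 Mb and over 50 Mb, -0.0349 to 0.110 for compartment strength and -0.022 to 0.063 for boundary strength. For the distal-to-local ratio they were -0.0042 to 0.011 in A, -0.016 to 0.0062 in B and -0.021 to 0.0068 near the centromere gap. That ratio gave -0.0020 to 0.023 on acrocentric, -0.0017 to 0.0069 on gene-poor and -0.0059 to 0.044 on gene-rich chromosomes. For insulation they were -0.0059 to 0.0062 in A and -0.0091 to 0.0087 in B. Insulation gave 0.0027 to 0.014 near chromosome ends and 0.0016 to 0.012 near the centromere gap. Its ranges were 4.2e-06 to 0.0026 on gene-rich and -0.0025 to -0.00018 on gene-poor chromosomes. Scaling to the mean of each chromosome holds these last values near the mean of all bins. Calls ranged from 0 to 59 for compartment scores, 0 to 2026 for the distal-to-local ratio, 3 to 3490 for insulation and 0 to 227 for domains. The highest counts came without NuMA-depleted 2, or without NuMA-depleted 1 for the distal-to-local ratio, which leaves 1 depleted library whose noise is taken from the wild type.

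No label says that a replicate number marks a shared day or culture. Deviations of same-numbered libraries from their group means correlated at -0.015 to 0.104 across bins and domains, 0.166 across coverage windows and -0.292 across chromosome pairs. Splitting the libraries by number gave 292 coverage windows at an unadjusted limma p under 0.05, against 8 by genotype and 37 by the crossed split. Libraries with number 1 were also the shallower of each genotype, so this split cannot part number from depth. With the number as a replicate block the calls were 5 for compartment scores, 78 for insulation and 2 for the distal-to-local ratio, and 0 for domains and chromosome pairs. The crossed pairing of chromosome pairs gave 0 calls. The gene lists and their alternative were not run. Depth limits single bins most in NuMA-depleted 1.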

Other observations

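The comparisons in this part were chosen after seeing the data. Contacts between chromosomes followed compartments and chromosome landmarks in every library. Bins of like compartment contacted each other more than unlike bins in 190 of the 190 chromosome pairs without 17, 19 and 22, whose contacts had set which sign was A. Among these chromosomes, A with A contacts stood at 1.28 ± 0.0480 times the mean in wild type and 1.304 ± 0.0112 after depletion, and A with B contacts at 0.790 ± 0.0531 and 0.771 ± 0.0130 (SD, n = 2). B with B contacts were close to the mean, at 1.01 ± 0.0404 and 1.02 ± 0.0221, with 0.986 and 1.04 in wild type and 1.03 and 1.00 after depletion. Over all chromosomes, regions near centromeres met those of other chromosomes at 2.11 ± 0.283 and 2.20 ± 0.115 times the mean, and chromosome ends at 2.05 ± 0.265 and 2.08 ± 0.0945. The exact p of each was 1.00.

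Joined chromosomes of the line were visible as strong contacts between chromosomes in all 4 libraries. HCT116 is known to carry derivative chromosomes that join parts of 8 with 16, 10 with 16 and 17 with 18. The 1 Mb window of chromosome 8 from 67000001 met that of chromosome 16 from 1 at 81.5 and 86.6 times the mean pair in wild type and 118.8 and 75.9 times after depletion. For chromosome 10 from 100000001 with chromosome 16 from 79000001 the values were 202 and 277 against 305 and 235, and for chromosome 17 from 43000001 with chromosome 18 from 1 they were 190 and 240.1 against 243 and 194. Another such contact joined chromosome 4 from 170000001 and chromosome 17 from 58000001, at 188 and 239.6 against 282 and 195. This chromosome 4 window lay between the bins from 160000001 and 175000001 named above for lower compartment scores. Whether the join bears on those scores was not tested. The windows were picked from the maps after their values were seen.

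Whole-contact coverage of 2800 windows of 1 Mb set wild type 2 apart: the SD of its log2 difference from each other library was 0.13 to 0.15, against 0.05 to 0.08 among the other 3. Limma called 0 windows between the genotypes, with 8 at an unadjusted p under 0.05, but without wild type 1 it called 307 higher and 168 lower. Boundaries called in each library at equal contacts numbered 2957 to 3009, and 65.9% to 69.2% of those of a library lay within 1 bin of a boundary of another, whatever their genotypes.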
